A study of Mus musculus with 12 samples.

How the data were processed

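Liver RNA from 12 male mice was measured on Affymetrix MOE430A arrays, 1 array per mouse. Per the labels, 3 mice were Mdr2-knockout and 3 were heterozygous controls at each of 2 ages, 3 and 12 months. Mdr2 is the earlier name of Abcb4, and the knockout is a mouse model of hepatocellular carcinoma. The groups are called Het_3M, KO_3M, Het_12M and KO_12M. The mice of the 2 ages are separate animals, as the series design text counts 3 males in each group. The source label of mouse 1 of Het_3M and of mouse 1 of KO_3M gives 12 months, whereas the title, the age field and the description stored with each array give 3 months. The title was followed, and leaving both arrays out was an alternative.

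The deposited values are MAS 5.0 signals, an intensity on a linear scale; the authors extracted them with MAS 5.0 software, per the series design text and the submitters' processing notes. The trimmed mean of each array, over the middle 2 to 98% of its probe sets, lay between 150.05 and 150.07, so the authors had already scaled the arrays. The scaling settings and any filter on dim probe sets are not given in the sources used here. The series design text names cluster analysis and fold change filtering, which were not repeated apart from a 2-fold filter tried as an alternative. The experiment descriptions stored with the arrays hold no measurement and were used only to find batches. The number of arrays limits the precision of every value.

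Each array was brought to 1 common trimmed mean, and 16 was added to each signal before taking log2. The offset makes fold changes of dim genes smaller than the ratio of their signals. Of 22690 probe sets, 64 are controls. A single gene symbol was given for 20380, several for 691, and no gene for 1619 (controls included). Symbols were updated through the gene ID to the RefSeq annotation of GRCm38.p6 for 20364 probe sets and kept as in the platform table for 29. These counts cover the whole platform table, with any controls it names, so together they exceed the 20380. Each of the 12393 gene symbols was represented by its probe set of highest mean log2 signal. A gene was tested when at least 3 of the 12 arrays reached the median of their own array, which left 8218 genes. No sequence or position of a probe was analysed here.

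The test was limma 3.58.1 in R 4.3.3 with an intensity trend (lmFit and eBayes). All 12 arrays were in a single fit with 4 group means and 8 residual degrees of freedom. The comparisons were knockout against heterozygous at 3 months and at 12 months, 12 against 3 months in each genotype, and the interaction, which is the knockout effect at 12 months minus that at 3 months. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 8218 genes. Adjusted p values in the text are limma's unless named otherwise, and an error after ± is a limma standard error for a gene's log2 fold change and an SD for a signal. For a mean over genes or a difference of list medians it is a standard error over genes. For a percentage kept under another fit it is a jackknife error over arrays. Fold changes are log2 throughout, with n = 3 mice in each group. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

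For the 41 lists, 27 of genes by function and 14 of cell type markers, camera of limma compared the members with all other tested genes at an inter-gene correlation of 0.01. Adjustment was over the 35 lists with at least 4 tested members. Each list was also tested with the correlation estimated from the data. "Adjusted over the list alone" means a Benjamini-Hochberg adjustment over the tested members of that list. Several lists share members; C1qa, C1qb and C1qc, for example, stand in both the complement and the macrophage list, and Lcn2 in 4 lists. Other lists hold 6 of the 17 tested macrophage markers, 3 of the 8 cholangiocyte, 2 of the 11 stellate cell and 6 of the 15 hepatocyte markers. On all 6 heterozygous arrays, 6 of the macrophage, 2 of the cholangiocyte, 3 of the stellate cell and 4 of the 14 endothelial markers lay at or above the median of the tested genes.

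Named genes were chosen by a rule. It takes Abcb4 and, for each knockout comparison, the 10 largest rises and the 10 largest falls among called genes whose 3 knockout arrays all lie on 1 side of the 3 heterozygous arrays. For the interaction and each age comparison it takes 5 of each, for the interaction without the condition on overlap. From each list called by camera or holding at least 3 called members it takes up to 4 members of smallest p in the direction of most called members, and the member of smallest p in the other direction. Clone-style names were counted but skipped. The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined.

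The fit was tested on simulated data with added changes among 8218 genes. For knockout against heterozygous at 3 months it called 35.8% of 1.5-fold, 77.6% of 2-fold and 97.0% of 4-fold changes, with 5 false calls. For the 12-month comparison it called 34.3%, 73.1% and 98.5% of these, with 3 false calls. For age it called 32.8%, 77.6% and 95.5% in the heterozygous mice with 4 false calls, and 28.4%, 80.6% and 98.5% in the knockout with 10. For the interaction it called 3.0%, 40.3% and 84.8%, with 4 false calls. A list shifted by 0.5 on the log2 scale among the 8218 genes of the 3-month comparison was called, and 0 of 34 other lists were. The genes were simulated independently of each other. The simulation therefore says nothing about false calls of lists whose members vary together.

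The arrays were scanned on 1 day in 3 sessions of 4 arrays, separated by gaps longer than 30 minutes, a limit set after the scan times were seen. Session 1 held Het_12M 1 to 3 and Het_3M 1. Session 2 held Het_3M 2 and 3 with KO_12M 1 and 2. Session 3 held KO_12M 3 and KO_3M 1 to 3. No session held both genotypes at 1 age, so no within-session knockout effect at a given age could be computed. In session 2 the knockout mice are also the older ones. With session as a block the knockout effects rest on chains of comparisons across sessions. The chain to 3 months runs through KO_12M 3 and that to 12 months through Het_3M 1. The session-blocked age effect compares KO_12M 3 with KO_3M in session 3 for the knockout and Het_12M with Het_3M 1 in session 1 for heterozygous mice. The session-blocked interaction is the difference of these. Each such fit thus rests on single arrays, so a call kept in it says little.

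Alternatives fixed beforehand were no rescaling, quantile normalization, scaling to the median, a smaller and a larger offset, no filter, a stricter filter at the upper quartile of the array, the mean of a gene's probe sets, every probe set on its own, no intensity trend, only the groups compared, array weights, mouse numbers as a replicate block, leaving out each array, leaving out the 2 arrays of disputed age, scan session as a block, a 2-fold filter alone and the estimated inter-gene correlation. Chosen after seeing the data were the 3' to 5' ratio of the actin and GAPDH controls as a covariate, leaving out the 2 arrays with a fluidics error, leaving out the 2 arrays run with another fluidics script, session as a random block, and camera on the age comparisons. The probe sets with several symbols or none were left out of the comparisons because they name no single gene.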

Results

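Expression was measured in the livers of 12 male mice, 3 in each of 4 groups: Mdr2-knockout and heterozygous control mice at 3 and at 12 months. Loss of Mdr2, the phospholipid transporter of the bile canaliculus now named Abcb4, leads to chronic bile duct inflammation and later to hepatocellular carcinoma. Each value is the MAS 5.0 signal of 1 probe set on 1 array, and the small number of arrays limits the precision of every comparison. Log2 signals correlated across genes between arrays of a group with r from 0.939 to 0.971, between the ages within a genotype from 0.931 to 0.969, and between the genotypes at 1 age from 0.897 to 0.938. Genes are not independent replicates in these correlations. Each of the 12 arrays had its highest correlation with an array of its own group.

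The groups also differed in measures of RNA quality and of the dim end of the signals. The 3' to 5' signal ratio of the actin control was 7.0 ± 1.6 in Het_3M, 4.9 ± 1.6 in KO_3M, 3.6 ± 0.6 in Het_12M and 2.8 ± 0.4 in KO_12M (SD, n = 3). That of GAPDH was 2.77, 1.57, 1.42 and 1.12 in the same order. The 10th percentile of the signals was 5.83 ± 0.15 in Het_3M and 4.40 ± 0.36 in KO_3M, against 6.13 ± 0.35 in Het_12M and 7.22 ± 1.89 in KO_12M. The arrays were scanned in 3 sessions, none of which held both genotypes at 1 age, so medians of lists with the session as a block are given beside the results, as are the values of many but not all named genes that lose their call with it.

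**Figure D1:**
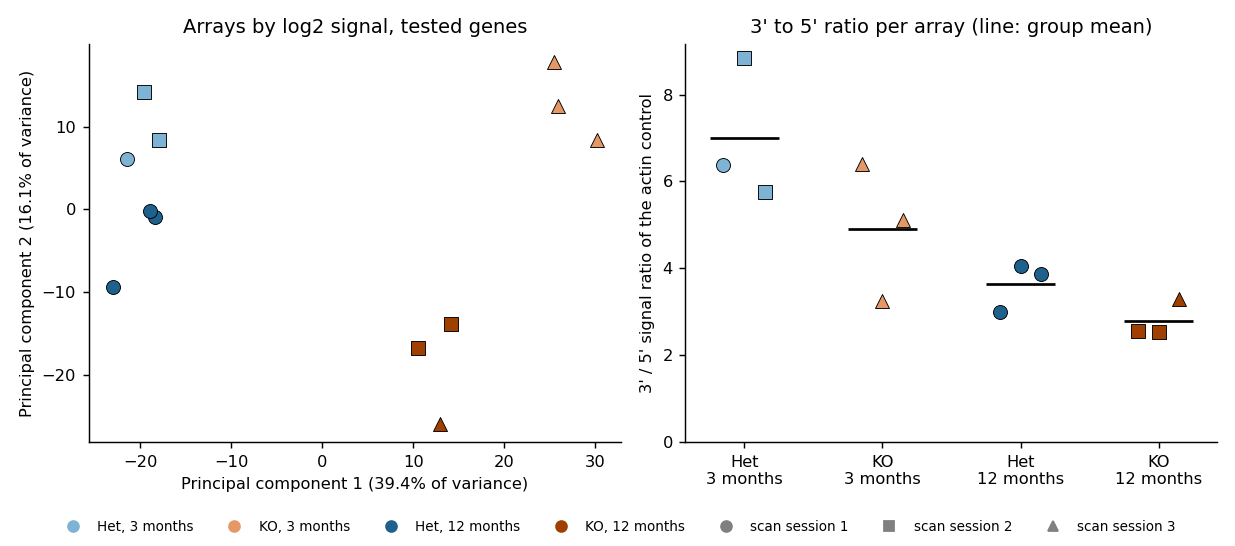
Left, the first 2 principal components of log2 signal over the tested genes, 1 point per array, with the genotypes apart on component 1 (39.4% of variance) and the ages on component 2 (16.1%). Right, the 3' to 5' signal ratio of the actin control per array (unitless; line, group mean), from a mean of 7.0 in Het_3M down to 2.8 in KO_12M; colour gives the group and shape the scan session.

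Abcb4 itself is read by 1 probe set on this array. Its signal was 728.7, 677.9 and 763.3 in the 3 Het_3M mice and 280.8, 295.5 and 385.7 in the KO_3M mice. At 12 months it was 591.8, 601.3 and 675.4 in the heterozygous and 293.2, 243.4 and 332.2 in the knockout mice. The knockout mean was thus 44.3% of the heterozygous mean at 3 months (320.7 ± 56.8 against 723.3 ± 43.0, SD) and 46.5% at 12 months (289.6 ± 44.5 against 622.8 ± 45.8). On the log2 scale Abcb4 fell by 1.15 ± 0.14 at 3 months (adjusted p = 3.95e-05) and by 1.07 ± 0.14 at 12 months (adjusted p = 0.000103). In the session-blocked fit the fall at 12 months was -1.15 at an adjusted p of 0.0512. Whether the probe set lies in the deleted part of the gene is not known, so the remaining signal says little about how complete the knockout is.

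The comparison at 3 months asks how knockout livers differed from heterozygous ones at the younger age of this cancer model. Lcn2, which binds iron-carrying siderophores, rose by 5.42 ± 0.43, from a signal of 4.87 ± 2.02 to 929 ± 364. The heterozygous signals of Lcn2, Bicc1 and Mcm5 lay below the 10th percentile, so the size of these changes is set by the added offset: it ran from 3.77 to 7.27 for Lcn2, 1.80 to 5.23 for Bicc1 and 1.39 to 4.21 for Mcm5 between the larger and the smaller offset. The sizes of other dim leading genes below depend on it too: 1.47 to 4.06 for Scara5, -1.46 to -3.53 for H2-T18, -1.28 to -4.24 for Cnmd, -1.26 to -4.10 for Insrr and -1.35 to -3.33 for Oas1e. Those of Hsd3b5 (-4.39 to -7.30), Ly6d (2.17 to 3.29), Cd36 (1.99 to 3.09) and Ubd (2.275 to 3.33) moved as well. The protease inhibitor Slpi rose by 3.97 ± 0.15, the phospholipid-binding annexin Anxa5 by 3.55 ± 0.29 and the RNA-binding protein Bicc1 by 3.25 ± 0.24. Hsd3b5, a steroid dehydrogenase of the male mouse liver, fell by 5.71 ± 0.51, and the fatty acid elongase Elovl3 by 2.89 ± 0.35.

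Further large rises at 3 months were those of the ubiquitin-like Ubd (2.97 ± 0.35), Ly6d (2.89 ± 0.23), the fatty acid transporter Cd36 (2.69 ± 0.25), the ferritin receptor Scara5 (2.69 ± 0.44), the replication helicase subunit Mcm5 (2.62 ± 0.37) and the lysozyme Lyz1 (2.57 ± 0.15). The other probe set of Scara5 read -0.48, and those of Lyz1 read -0.60 and 1.40. Large falls were those of Cyp2c54 (-2.64 ± 0.14), the organic anion transporter Slc22a7 (-2.57 ± 0.27), H2-T18 (-2.53 ± 0.42), Cnmd (-2.53 ± 0.36) and the receptor Insrr (-2.46 ± 0.30). Cyp7b1, an oxysterol hydroxylase of bile acid synthesis, fell by 2.37 ± 0.25. Oas1e (-2.36 ± 0.29) and the carboxylesterase Ces1e (-2.22 ± 0.14) fell too. The adjusted p of these 20 genes was at most 0.000549, which was that of H2-T18, and each had all 3 knockout arrays on 1 side of the 3 heterozygous arrays. Under the session block Ubd (2.18), Mcm5 (1.58), Elovl3 (-1.09), Slc22a7 (-1.36), H2-T18 (-0.18), Insrr (-1.63) and Cyp7b1 (-1.63) no longer passed.

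**Figure D2:**
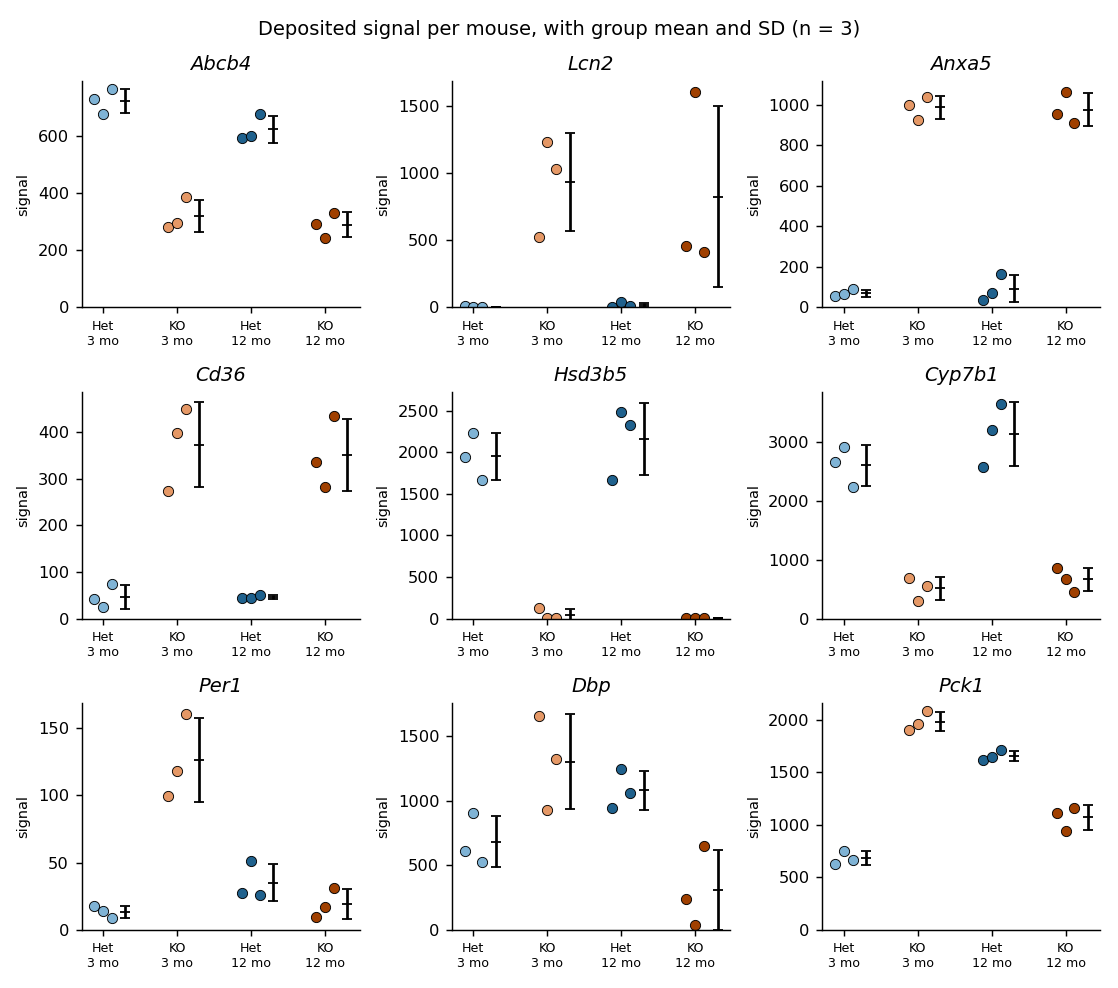
Deposited MAS 5.0 signal (intensity, linear scale) of 9 named genes, 1 point per mouse, with the mean and SD of each group of 3. Lcn2, Anxa5 and Cd36 are higher and Hsd3b5 and Cyp7b1 lower in both knockout groups, while Per1, Dbp and Pck1 are highest in KO_3M.

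Matrix, mesenchymal and ductular lists were higher in the knockout at 3 months. Among 27 tested genes of the extracellular matrix, 18 rose, 0 fell and 9 did not pass (19 passed adjusted over the list alone); the median was 0.79 with a camera adjusted p = 4.04e-11, and adjusted p = 0.0104 with an estimated correlation. Collagen Col3a1 rose by 2.40 ± 0.20, the proteoglycans Lum by 1.97 ± 0.22 and Bgn by 1.31 ± 0.13, and the intermediate filament Vim by 1.43 ± 0.18. The annexin, S100 and cytoskeleton list had 12 of 19 genes higher and 0 lower (15 adjusted over the list alone), a median of 0.84 and a camera adjusted p = 3.44e-10, with adjusted p = 0.0518 with an estimated correlation. Its galectin Lgals1 rose by 2.29 ± 0.12 and Anxa2 by 1.69 ± 0.15, although 1 of the 2 other probe sets of Anxa2 read -0.34. Stellate cell and fibroblast markers rose in 7 of 11 and fell in 0 (8 adjusted over the list alone), with a median of 0.84 and a camera adjusted p = 0.000906, and adjusted p = 0.142 with an estimated correlation. Mgp rose by 1.44 ± 0.23 and Dcn by 1.00 ± 0.15. Cholangiocyte markers rose in 5 of 8 and fell in 0 (6 adjusted over the list alone), with a median of 1.15 and a camera adjusted p = 0.000296, and adjusted p = 0.0518 with an estimated correlation. The keratins Krt23 (2.29 ± 0.37), Krt8 (1.24 ± 0.16) and Krt18 (1.15 ± 0.17) and E-cadherin Cdh1 (1.14 ± 0.15) were among them. When session was blocked, the medians of these 4 lists were 0.96, 1.10, 0.89 and 1.30, and all 4 passed. Krt23 (1.33) lost its call there.

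Macrophage and Kupffer cell markers rose at 3 months in 13 of 17 and fell in 2 (16 adjusted over the list alone), with a median of 1.33 and a camera adjusted p = 9.74e-11, and adjusted p = 0.0518 with an estimated correlation. The complement subunits C1qa and C1qc rose by 2.03 ± 0.22 and 1.90 ± 0.22, lysozyme Lyz2 by 1.99 ± 0.16 and galectin Lgals3 by 1.58 ± 0.18, whereas Trem2 fell by 1.07 ± 0.21, with its other probe set at 0.35. MHC class II genes rose in 5 of 7 and fell in 0 (6 adjusted over the list alone), with a median of 1.01 and a camera adjusted p = 2.73e-05, and adjusted p = 0.0415 with an estimated correlation. The invariant chain Cd74 rose by 1.57 ± 0.15. Interferon response genes rose in 10 of 16 and fell in 0 (10 adjusted over the list alone), with a median of 1.22 and a camera adjusted p = 4.45e-07, and adjusted p = 0.252 with an estimated correlation. The immunoproteasome subunits Psmb9 and Psmb8 rose by 2.18 ± 0.22 and 2.07 ± 0.28. Chemokine and inflammatory genes rose in 9 of 19 and fell in 0 (12 adjusted over the list alone), with a median of 0.48 and a camera adjusted p = 0.000153, and adjusted p = 0.0985 with an estimated correlation. The lipopolysaccharide receptor Cd14 rose by 2.11 ± 0.30 and the adhesion molecule Icam1 by 2.01 ± 0.36. With the session blocked the medians were 1.28 for macrophage, 0.91 for MHC class II, 0.97 for interferon and 0.91 for chemokine genes, and each list passed. In that fit the calls of Cd14 (2.23), Psmb8 (1.94), Icam1 (1.89) and Trem2 (-1.28) were lost.

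Acute phase genes rose at 3 months in 4 of 19 and fell in 1 (5 adjusted over the list alone), with a median of 0.22 and a camera adjusted p = 0.0233, and adjusted p = 0.612 with an estimated correlation. Serum amyloid Saa1 rose by 2.48 ± 0.34 and the serpin Serpina3n by 0.93 ± 0.13. Complement and coagulation genes rose in 8 of 30 and fell in 0 (10 adjusted over the list alone), with a median of 0.03 and a camera adjusted p = 0.0328, lost under quantile normalization (0.0824), with the mean of probe sets (0.0593) and without the arrays of the other fluidics script (0.0589), and adjusted p = 0.514 with an estimated correlation. Besides C1qa and C1qc, C6 rose by 1.10 ± 0.16 and C2 by 0.98 ± 0.14. Immediate early and heat shock genes rose in 6 of 19 and fell in 0 (7 adjusted over the list alone), with a median of 0.52 and a camera adjusted p = 0.00608, and adjusted p = 0.252 with an estimated correlation. The transcription factors Klf6 and Jun rose by 1.70 ± 0.31 and 0.92 ± 0.22, though 1 of the 2 other probe sets of Klf6 read -0.08. A stricter filter ended the call of each of the 3 lists, with medians of 0.13 (0.0915) for acute phase, 0.03 (0.117) for complement and 0.32 (0.137) for immediate early genes. With session as a block the 3 medians were 0.58, 0.37 and 0.59. These blocked values include KO_12M 3 against KO_3M in session 3, where the acute phase median was -0.505, the complement median -0.449 and the immediate early median -0.292. Klf6 (1.43) and Serpina3n (0.93) lost their calls in that fit.

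Cell cycle and mitosis genes rose at 3 months in 9 of 21 and fell in 0 (12 adjusted over the list alone), with a median of 0.61 and a camera adjusted p = 1.32e-06, and adjusted p = 0.0947 with an estimated correlation. The polymerase clamp Pcna rose by 1.38 ± 0.18, the mitotic kinase Cdk1 by 1.59 ± 0.24 and the nucleotide reductase subunit Rrm1 by 1.59 ± 0.27. G1 regulators and growth arrest genes rose in 9 of 18 and fell in 1 (10 adjusted over the list alone), with a median of 0.34 and a camera adjusted p = 0.00446, and adjusted p = 0.0985 with an estimated correlation. Cyclin Ccnd1 rose by 1.79 ± 0.18 and the inhibitor Cdkn1a by 1.47 ± 0.33, with the other probe set of Cdkn1a at -0.16, and cyclin Ccne1 fell by 0.97 ± 0.21. The liver cancer and fetal liver list had 4 of 11 genes higher and 1 lower (5 adjusted over the list alone), with a median of 0.42 and a camera adjusted p = 0.0167, and adjusted p = 0.142 with an estimated correlation. Without KO_3M 3 its adjusted p was 0.072. Ly6d and Lcn2 belong to it, as do the Golgi protein Golm1 (0.97 ± 0.19) and the imprinted Peg3, which fell by 1.22 ± 0.15. Under the session block the medians were 0.62, 0.46 and -0.11, and camera called each list higher, the last against the sign of its median. Cdk1 (1.04), Rrm1 (1.42) and Ccne1 (-0.92) did not pass there.

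Among metabolic lists at 3 months, drug-metabolising cytochromes P450 rose in 0 of 17 and fell in 8 (9 adjusted over the list alone), with a median of -0.38 and a camera adjusted p = 0.0185, and adjusted p = 0.31 with an estimated correlation. Cyp2c37 fell by 1.38 ± 0.23 and Cyp1a2 by 1.13 ± 0.17, and with session as a block the median was -0.21 and the list did not pass (adjusted p = 0.739). Male-biased liver genes rose in 2 of 18 and fell in 6 (10 adjusted over the list alone), with a median of -0.18, which became 0.15 with session as a block and 0.003 under median scaling; the camera adjusted p = 0.0431, and adjusted p = 0.612 with an estimated correlation. Hsd3b5, Elovl3 and Cyp7b1 account for the largest of these falls, and C6 rose. The male-biased list lost its call without Het_3M 2 (0.083), KO_3M 2 (0.0917), KO_3M 3 (0.134), Het_12M 2 (0.0518), KO_12M 2 (0.0509) or both arrays with a fluidics error (0.0803). It did so too with the smaller offset (0.0651), no filter (0.0521), no intensity trend (0.0709), array weights (0.059) and the 3' to 5' ratio as a covariate (median -0.10, 0.402). Cholesterol synthesis genes rose in 5 of 19 and fell in 1 (7 adjusted over the list alone), with a median of 0.27 and a camera adjusted p = 0.0417, and adjusted p = 0.586 with an estimated correlation. Its call was lost under quantile normalization (0.113), a stricter filter (0.117), the mean of probe sets (median 0.10, 0.247), no intensity trend (0.0525) and only the groups compared (0.0506). It was also lost with session as a block (0.319), with the ratio (median 0.07, 0.327) and without Het_3M 3 (0.137), KO_3M 2 (0.145), KO_3M 3 (0.134) or both arrays with a fluidics error (0.0544). The transcription factor Srebf2 rose by 0.75 ± 0.15, Fdps by 1.30 ± 0.20 with its other probe set at -0.01, and the reductase Tm7sf2 fell by 0.56 ± 0.12. The session block also ended the calls of Cyp2c37 (-1.50), Cyp1a2 (-0.88), Srebf2 (1.02), Fdps (1.21) and Tm7sf2 (-0.53).

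The other 18 tested lists did not pass at 3 months. Bile acid genes rose in 1 of 19 and fell in 5 (8 adjusted over the list alone), with a median of -0.19 and an adjusted p of 0.147: besides Cyp7b1, the sterol hydroxylase Cyp8b1 fell by 1.42 ± 0.30, the repressor Nr0b2 by 1.64 ± 0.26 and the bile acid importer Slc10a1 by 0.56 ± 0.13. Cyp7a1, the rate-limiting enzyme of the pathway, rose by 1.08 ± 0.28, and did not pass without Het_3M 3 (0.94, 0.0521) or KO_3M 3 (0.76, 0.0649). Fatty acid oxidation genes fell in 5 of 19 (5 adjusted over the list alone; median -0.17, 0.0888), among them the thioesterase Acot1 (-2.19 ± 0.22). Glutathione and NRF2 targets rose in 5 of 22 and fell in 2 (8 adjusted over the list alone; 0.15, 0.0552), and Gstm3 rose by 1.60 ± 0.17. Lipoprotein genes rose in 3 of 18 (3 adjusted over the list alone), with a median of -0.03, a mean of 0.19 and an adjusted p of 0.131; lipoprotein lipase Lpl rose by 2.09 ± 0.15. Gluconeogenesis and glycolysis genes rose in 3 of 17 and fell in 1 (6 adjusted over the list alone; 0.09, 0.117), with Pck1 at 1.53 ± 0.12. Clock genes rose in 2 of 12 and fell in 2 (4 adjusted over the list alone; 0.44, 0.199), with Per1 at 2.28 ± 0.32, or 1.68 and not passing in the session-blocked fit (0.11). Hepatocyte markers rose in 1 of 15 and fell in 2 (3 adjusted over the list alone; -0.02, 0.885). The calls of Nr0b2 (-0.93), Cyp8b1 (-0.63), Slc10a1 (-0.49) and Cyp7a1 (0.79) were likewise lost with session blocked.

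For the remaining 11 lists the median at 3 months and the camera adjusted p were -0.04 and 0.852 for fatty acid synthesis, 0.13 and 0.447 for metallothioneins and iron, -0.03 and 0.885 for the urea cycle and amino acids, -0.10 and 0.735 for female-biased genes, and -0.25 and 0.218 for endoplasmic reticulum stress. They were -0.14 and 0.3 for oxidative phosphorylation, -0.04 and 0.852 for ribosomal proteins, -0.08 and 0.874 for T and natural killer cells, -0.16 and 0.874 for B and plasma cells, -0.34 and 0.631 for neutrophils and 0.04 and 0.634 for endothelial cells. Medians and means had opposite signs for B cells (mean 0.16) and neutrophils (mean 0.26), and camera placed the urea cycle list higher against its median. In the same order 0, 1, 2, 1, 0, 1, 0, 1, 1, 1 and 1 members rose and 2, 1, 2, 2, 2, 0, 0, 1, 1, 1 and 1 fell, and adjusted over the list alone the passing members numbered 1, 2, 4, 4, 1, 0, 0, 3, 2, 2 and 1. Lists with fewer than 4 tested members had no test: 1 of 3 erythroid, 0 of 3 platelet and 0 of 3 adipocyte genes were called, 2 of 3 pancreatic acinar and 1 of 2 muscle genes fell, and no mesothelial gene was tested. When session was blocked, hepatocyte markers had a median of 0.59, lipoprotein genes 0.39, metallothioneins 0.37, the urea cycle 0.25, gluconeogenesis 0.22, ribosomal proteins 0.23 and glutathione genes 0.19. That fit reaches 3 months through KO_12M 3 alone, whose hepatocyte median against KO_3M in session 3 was -0.71. In session 2 the hepatocyte median of KO_12M against Het_3M was -0.20, so the blocked rise of hepatocyte markers rests on that array.

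In total 1820 of 8218 genes were called at 3 months, 813 higher and 1007 lower in the knockout, of which 308 and 231 changed at least 2-fold. At an unadjusted p under 0.05 there were 2936 genes, against 411 by chance. The split depended on the scaling: median scaling gave 1331 higher and 518 lower and moved the median of all genes from -0.06 to 0.11, and quantile normalization gave 807 and 808. Among the 2740 dimmest of the tested genes 233 were higher and 389 lower (quantile normalization 277 and 248), and among the 2739 brightest 344 and 277. The count was 291 with session as a block, 679 with the 3' to 5' ratio as a covariate and 1022 without both arrays of disputed age.

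The comparison at 12 months asks how the knockout liver differed at the older age. Of its 20 leading genes 10 were also among those of 3 months. Lcn2 rose by 4.46 ± 0.43, Ly6d by 3.90 ± 0.23, Anxa5 by 3.38 ± 0.29 and Slpi by 3.23 ± 0.15, and Hsd3b5 fell by 6.60 ± 0.51. The nucleoside phosphorylase Upp2 fell by 3.11 ± 0.27 and the clock output gene Dbp by 2.37 ± 0.55.

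Other large rises at 12 months were those of prostaglandin D synthase Ptgds (3.08 ± 0.26), Bicc1 (2.94 ± 0.24), the basement membrane proteins Tinag (2.88 ± 0.28) and Nid1 (2.58 ± 0.15), macrophage elastase Mmp12 (2.83 ± 0.36) and the reticulon Rtn4 (2.76 ± 0.16). Cyp2c54 fell by 2.42 ± 0.14, Slc22a7 by 2.37 ± 0.27, the thyroid hormone deiodinase Dio1 by 2.33 ± 0.27, Cyp7b1 by 2.24 ± 0.25, the lysosomal transporter Slc66a1 by 2.21 ± 0.26, Cnmd by 2.20 ± 0.36 and Ly6i by 2.00 ± 0.35. The adjusted p of these 20 genes was at most 0.00931, that of Dbp, and in each the 3 knockout arrays lay on 1 side of the 3 heterozygous arrays. With the session blocked Slc22a7 (-1.56) and Ly6i (-1.75) no longer passed. The signals of Tinag and Mmp12 in heterozygous and of Hsd3b5 in knockout mice lay below the 10th percentile of their groups. Their changes ran from 1.52 to 4.75 for Tinag, 1.47 to 4.81 for Mmp12 and -4.97 to -8.27 for Hsd3b5 between the larger and the smaller offset. Those of Bicc1 (1.67 to 4.35), Cnmd (-1.26 to -3.20) and Ly6i (-1.03 to -3.09) depended on it too, as did those of Lcn2 (3.21 to 5.57), Ly6d (2.82 to 4.63) and Slc66a1 (-1.43 to -2.74).

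Matrix, ductular and macrophage lists were again higher. Of the 27 matrix genes 16 rose, 0 fell and 11 did not pass (20 adjusted over the list alone), with a median of 0.73 and a camera adjusted p = 8.84e-14, and adjusted p = 0.0054 with an estimated correlation. Lum rose by 1.90 ± 0.22 and Bgn by 1.12 ± 0.13. In the annexin, S100 and cytoskeleton list 13 of 19 rose and 0 fell (15 adjusted over the list alone), with a median of 1.19 and a camera adjusted p = 1.19e-16, and adjusted p = 0.0158 with an estimated correlation. Lgals1 rose by 2.13 ± 0.12 and Anxa2 by 2.01 ± 0.15. For cholangiocyte markers 4 of 8 rose and 0 fell (5 adjusted over the list alone), with a median of 0.86 and a camera adjusted p = 4.17e-06, and adjusted p = 0.0173 with an estimated correlation. Cdh1 rose by 1.63 ± 0.15. Stellate cell and fibroblast markers rose in 5 of 11 and fell in 1 (9 adjusted over the list alone), with a median of 0.79 and a camera adjusted p = 0.000256, and adjusted p = 0.0989 with an estimated correlation. The growth factor receptor Pdgfrb rose by 1.69 ± 0.24 and Ecm1 fell by 0.59 ± 0.13. Macrophage markers rose in 11 of 17 and fell in 0 (12 adjusted over the list alone), with a median of 0.72 and a camera adjusted p = 4.61e-11, and adjusted p = 0.0357 with an estimated correlation. Lyz2 rose by 2.01 ± 0.16 and Cd14 by 2.39 ± 0.30. In the session-blocked fit the medians were 0.82, 1.32, 0.89, 0.94 and 0.96, and each list passed. Within session 2, where the 2 knockout mice were 12 and the 2 heterozygous mice 3 months old, the medians were 0.83 for matrix, 1.19 for annexin, 0.97 for cholangiocyte and 1.20 for macrophage genes, and 0.06 for endothelial markers. Pdgfrb (1.31), Cd14 (2.33) and Ecm1 (-0.68) lost their calls in the session-blocked fit.

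MHC class II genes rose at 12 months in 5 of 7 (5 adjusted over the list alone), with a median of 0.92 and a camera adjusted p = 3.02e-05, and adjusted p = 0.0184 with an estimated correlation. H2-Aa rose by 0.83 ± 0.13. Chemokine and inflammatory genes rose in 6 of 19 (8 adjusted over the list alone), with a median of 0.34 and a camera adjusted p = 0.00305, and adjusted p = 0.139 with an estimated correlation. A stricter filter left a median of 0.01 and ended the call (0.0586). Interferon response genes rose in 3 of 16 (4 adjusted over the list alone), with a median of 0.23 and a camera adjusted p = 0.0206, and adjusted p = 0.553 with an estimated correlation. The call was lost without KO_3M 2 (0.0734), KO_3M 3 (0.0593) or KO_12M 2 (0.0523), with the larger offset (median 0.12, 0.0865) and with the 3' to 5' ratio as a covariate (median 0.01, 0.215). G1 regulators rose in 9 of 18 (11 adjusted over the list alone), with a median of 0.80 and a camera adjusted p = 3.42e-06, and adjusted p = 0.0173 with an estimated correlation. Ccnd1 rose by 1.33 ± 0.18 and Btg2 by 1.29 ± 0.18. Cell cycle genes rose in 8 of 21 and fell in 1 (11 adjusted over the list alone), with a median of 0.57 and a camera adjusted p = 2.9e-05, and adjusted p = 0.0989 with an estimated correlation. The liver cancer and fetal liver list rose in 4 of 11 (6 adjusted over the list alone), with a median of 0.87 and a camera adjusted p = 8.89e-05, and adjusted p = 0.0344 with an estimated correlation. Golm1 rose by 1.10 ± 0.19. Glutathione and NRF2 targets rose in 7 of 22 (7 adjusted over the list alone), with a median of 0.25 and a camera adjusted p = 0.0089, and adjusted p = 0.139 with an estimated correlation. Gstm3 rose by 1.79 ± 0.17. Of these lists only the last lost its call with session as a block (median 0.09, 0.165). H2-Aa (0.54), Btg2 (1.40) and Golm1 (1.17) lost theirs as well.

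Male-biased genes fell at 12 months in 9 of 18 and rose in 0 (11 adjusted over the list alone), with a median of -0.65 and a camera adjusted p = 3.89e-09, and adjusted p = 0.118 with an estimated correlation. The hydrolase Nudt7 fell by 1.23 ± 0.17. Cytochromes P450 fell in 6 of 17 and rose in 2 (12 adjusted over the list alone), with a median of -0.38 and a camera adjusted p = 0.000335, and adjusted p = 0.118 with an estimated correlation. Cyp1a2 fell by 1.40 ± 0.17 and Cyp2c38 rose by 1.27 ± 0.16. Bile acid genes fell in 8 of 19 and rose in 1 (9 adjusted over the list alone), with a median of -0.32 and a camera adjusted p = 0.000257, and adjusted p = 0.0931 with an estimated correlation. Slc10a1 fell by 0.87 ± 0.13 and the bile salt exporter Abcb11 rose by 0.65 ± 0.13. Fatty acid oxidation genes fell in 6 of 19 and rose in 1 (10 adjusted over the list alone), with a median of -0.39 and a camera adjusted p = 0.000143, and adjusted p = 0.0579 with an estimated correlation. The kinase Pdk4, which restrains glucose oxidation, rose by 2.11 ± 0.34. Clock genes fell in 5 of 12 and rose in 0 (7 adjusted over the list alone), with a median of -0.70 and a camera adjusted p = 0.000256, and adjusted p = 0.118 with an estimated correlation. With session as a block these 5 medians were -0.58, -0.45, -0.19, -0.31 and -0.72, and each list passed. Pdk4 (0.90), Nudt7 (-0.83), Slc10a1 (-0.82), Abcb11 (0.54) and Cyp2c38 (1.13) did not pass there.

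Urea cycle and amino acid genes fell in 7 of 22 (10 adjusted over the list alone), with a median of -0.33, which was -0.14 with session as a block (0.153); the camera adjusted p = 3.29e-05, and adjusted p = 0.139 with an estimated correlation. The methionine adenosyltransferase Mat1a fell by 0.99 ± 0.19 and arginase Arg1 by 0.72 ± 0.16. The calls of 5 further lists were each lost under quantile normalization and with session as a block. Hepatocyte markers fell in 2 of 15 (5 adjusted over the list alone), with a median of -0.34 (session block -0.08), a camera adjusted p = 0.000151 and adjusted p = 0.299 with an estimated correlation. Complement and coagulation genes fell in 5 of 30 and rose in 3 (10 adjusted over the list alone), with a median of -0.17 (session block -0.01), a camera adjusted p = 0.0243 and adjusted p = 0.415 with an estimated correlation. Factor F11 fell by 1.08 ± 0.13. Endoplasmic reticulum stress genes fell in 2 of 20 (2 adjusted over the list alone), with a median of -0.18 (session block 0.14), a camera adjusted p = 0.0205 and adjusted p = 0.328 with an estimated correlation. Oxidative phosphorylation genes fell in 1 of 34 (0 adjusted over the list alone), with a median of -0.16 (session block -0.13), a camera adjusted p = 0.0122 and adjusted p = 0.395 with an estimated correlation. Ribosomal protein genes fell in 0 of 21 (0 adjusted over the list alone), with a median of -0.22 (session block 0.02), a camera adjusted p = 0.0109 and adjusted p = 0.406 with an estimated correlation. The last 4 lost their calls without KO_12M 3 (0.262, 0.162, 0.135 and 0.124), complement (0.12), oxidative phosphorylation (0.0878) and ribosomal genes (0.0624) also without Het_12M 2, and the stress list without KO_12M 1 (0.0602). Without the arrays of the other fluidics script these 4 lost them too (0.255, 0.165, 0.127 and 0.124). A stricter filter ended the calls of complement (0.102), stress (0.0995) and oxidative phosphorylation genes (0.0649), and the ratio those of complement (0.0612), oxidative phosphorylation (0.134) and ribosomal genes (0.0597). Complement genes did not pass with only the groups compared (0.0613) or array weights (0.112), nor the stress list with the mean of probe sets (0.119). Arg1 (-0.21), Mat1a (-1.01) and F11 (-0.99) lost their calls with session blocked.

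The other 12 tested lists did not pass at 12 months. Medians and adjusted p were 0.07 and 0.622 for cholesterol synthesis, -0.02 and 0.996 for fatty acid synthesis, 0.01 and 0.42 for metallothioneins, 0.14 and 0.609 for acute phase genes, and 0.03 and 0.895 for gluconeogenesis. They were 0.29 and 0.42 for female-biased genes, 0.24 and 0.114 for immediate early genes, 0.07 and 0.643 for T cells, 0.07 and 0.587 for B cells, 0.11 and 0.37 for neutrophils and 0.20 and 0.0935 for endothelial cells. In the order given 0, 2, 2, 2, 1, 2, 4, 1, 0, 1 and 1 members rose and 1, 2, 0, 2, 2, 0, 0, 0, 0, 0 and 0 fell, with 4, 4, 2, 6, 5, 3, 8, 1, 0, 1 and 1 passing adjusted over the list alone. Of the lists without a test, 1 erythroid and 1 adipocyte gene rose and 1 erythroid and 1 pancreatic acinar gene fell. When session was blocked, acute phase (0.23, 0.0136) and immediate early genes (0.55, 0.00433) passed. Lipoprotein genes, with 4 of 18 higher and 1 lower (9 adjusted over the list alone), had a median of -0.28 and a mean of 0.05 (0.643), while Lpl rose by 2.18 ± 0.15, Apoc2 by 1.22 ± 0.13 and Apoa4 by 1.38 ± 0.16. The early gene Egr1 rose by 1.40 ± 0.28 and the fatty acid synthase Fasn by 0.90 ± 0.19, and Pck1 fell by 0.63 ± 0.12, with its other probe set at 0.50. Fasn (1.02) and Pck1 (-0.86) lost their calls in that fit.

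At 12 months 889 genes were called, 525 higher and 364 lower, 212 and 71 of them at least 2-fold, and 1998 genes had an unadjusted p under 0.05. Median scaling gave 385 higher and 460 lower. Among the 2740 dimmest genes 154 were higher and 52 lower (quantile normalization 134 and 79), and among the 2739 brightest 173 and 248 (216 and 244). On all 6 heterozygous arrays 15 of 15 hepatocyte, 34 of 34 oxidative phosphorylation, 28 of 30 complement, 21 of 22 urea cycle and 19 of 21 ribosomal genes lay above the median of the tested genes, against 4 of 12 clock genes. So did 15 of 18 male-biased, 15 of 17 cytochrome P450, 16 of 19 bile acid, 16 of 19 fatty acid oxidation and 15 of 20 endoplasmic reticulum stress genes. The falls of all these bright lists are thus not separated from brightness. Under quantile normalization the male-biased, cytochrome P450, bile acid, fatty acid oxidation and urea cycle lists still passed. With the session blocked 114 genes were called.

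**Figure D3:**
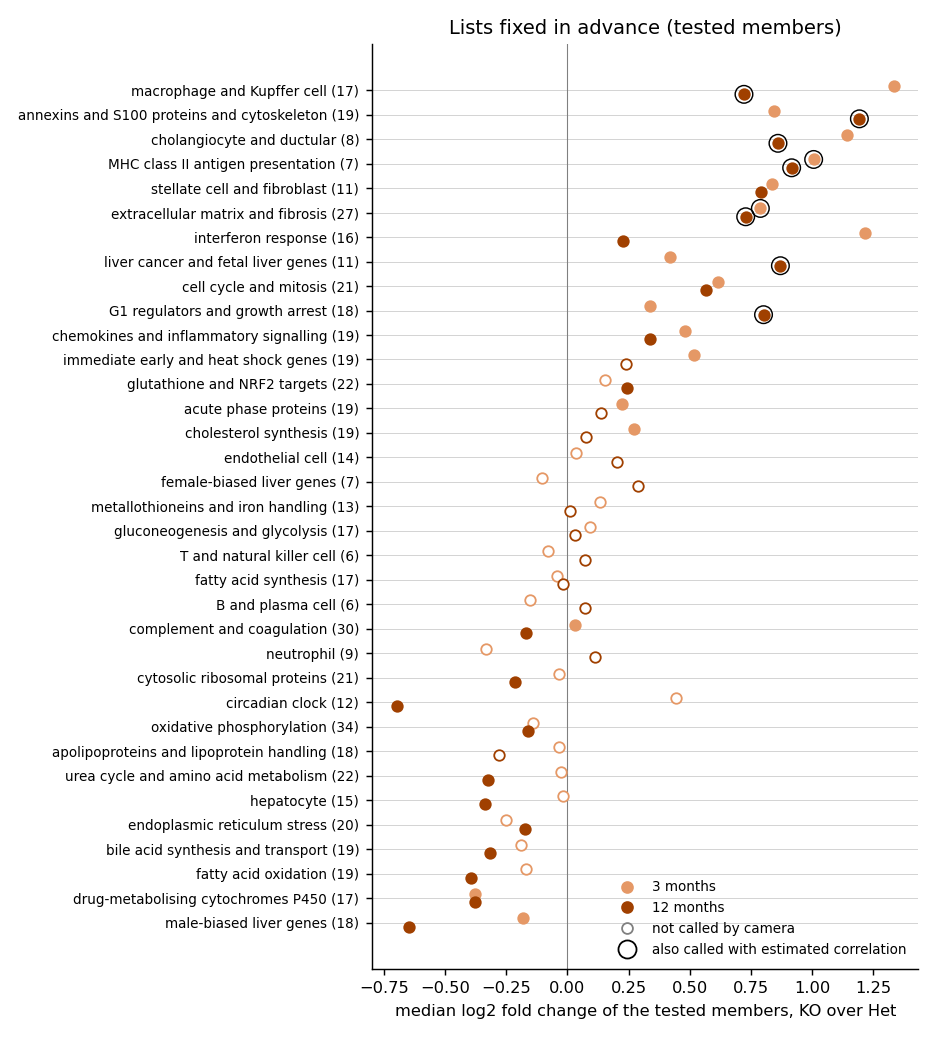
Median log2 fold change of the tested members of each list, knockout over heterozygous, at 3 months (light) and 12 months (dark), with the number of tested members in brackets; filled points were called by camera, ringed points also with an estimated correlation. Matrix (0.79 and 0.73) and MHC class II (1.01 and 0.92) lists are ringed at both ages; the male-biased median at 3 months (-0.18) is 0.003 under median scaling.

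The knockout effects at the 2 ages were compared directly. In both comparisons 472 genes were called in the same direction, 327 higher where 51.9 would be shared by chance and 145 lower where 44.6 would be (one-sided Fisher's exact test across genes, p = 1.39e-215 and p = 5.32e-43). Genes are not independent, so these p values overstate the evidence. No array enters the log2 changes of both comparisons, but both take each gene's spread from the same fit of 12 arrays. Genes of small spread are thus more readily called at both ages, which can raise the overlap above these chance values. Across all 8218 genes the log2 changes correlated with r = 0.602 ± 0.039 (jackknife over arrays) and rho = 0.48, and 83.5% of the genes called at 3 months had the same sign at 12 months, with a slope of 0.534. Only 13 genes were called in opposite directions. Of these, Upp2 (1.08 and -3.11), Usp2 (1.92 and -1.40), Map2k6 (1.02 and -1.17), Pck1 (1.53 and -0.63), Klf15 (0.95 and -0.60) and Akr1c12 (0.62 and -0.55) were higher at 3 and lower at 12 months. Clpx (-0.99 and 0.72), Id3 (-0.53 and 0.93), Ndrg1 (-0.67 and 0.93), Lgalsl (-0.67 and 0.93), Insig2 (-0.66 and 0.80), Plin5 (-0.70 and 0.60) and Egln3 (-0.47 and 0.54) went the other way. None of the 13 was called at both ages in the session-blocked fit, where 10 kept opposite signs. Only Pck1 at 3 months (1.28) and Upp2 at 12 months (-3.57) were called there, and Upp2 (-0.08), Insig2 (0.20) and Lgalsl (0.19) changed sign at 3 months. In the session-blocked fit 63 genes were shared and r was 0.548.

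**Figure D4:**
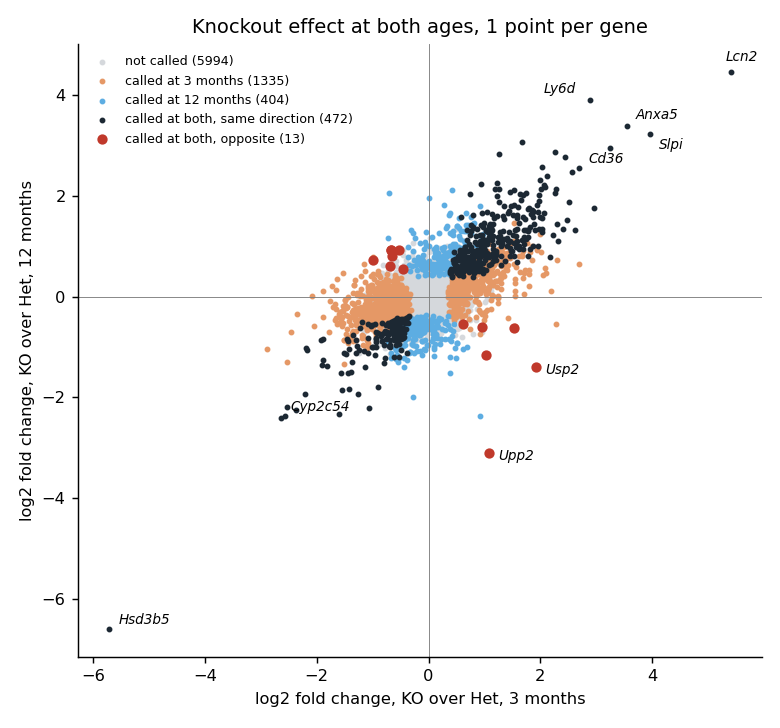
Log2 fold change, knockout over heterozygous, at 3 months (x axis) and 12 months (y axis), 1 point per tested gene. The 472 genes called at both ages in the same direction run along the diagonal from Hsd3b5 to Lcn2, and 13 genes called in opposite directions, among them Upp2 and Usp2, lie in the other quadrants.

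The age comparison in heterozygous mice asks what differed between 3 and 12 months without the knockout. Few genes were called. Pck1, the enzyme that commits to gluconeogenesis, rose by 1.27 ± 0.12, although its other probe set read -0.10, and the growth factor receptor Gfra1 rose by 1.48 ± 0.30, the kinase Map2k6 by 1.40 ± 0.28, Upp2 by 1.31 ± 0.27 and the dynactin subunit Dctn5 by 1.23 ± 0.20. The carboxylase Acacb fell by 2.30 ± 0.40, metallothionein Mt1 by 1.36 ± 0.27, Nr0b2 by 1.30 ± 0.26, the splicing factor Rbm22 by 1.25 ± 0.24 and Derl1 by 1.21 ± 0.21, while the other probe sets of Mt1 (0.37) and Derl1 (0.07 to 0.17) read higher. With session as a block this age effect compares Het_12M with Het_3M 1 alone, an array of disputed age. There Gfra1 was 1.65, Map2k6 1.17, Upp2 1.36, Acacb -2.05, Mt1 -1.52, Nr0b2 -1.45, Rbm22 -1.49 and Derl1 -1.03. Of all genes named for age in heterozygous mice only Pck1 passed in every omission of 1 array. Abcb4 had -0.21 ± 0.14 (adjusted p = 0.524).

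Camera, applied to the age comparisons after seeing the data, called 4 lists in heterozygous mice. Clock genes had a median of 0.68 and cholesterol synthesis genes 0.24 (2 of 19 rose, among them Fdps by 1.17 ± 0.20), while fatty acid synthesis genes had -0.17 and oxidative phosphorylation genes -0.13. Their adjusted p was 0.00705, 0.0114, 0.00705 and 0.00705, and adjusted p = 0.777 for each with an estimated correlation. No clock or oxidative phosphorylation member passed by itself, while 2 and 0 did adjusted over the list alone. With session as a block, Het_12M against Het_3M 1 alone, the medians were 0.55 for clock, 0.03 for cholesterol synthesis, -0.18 for fatty acid synthesis and -0.12 for oxidative phosphorylation genes. Fdps was 0.77 there. Under quantile normalization the fatty acid synthesis (0.109) and oxidative phosphorylation (0.284) lists did not pass.

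In heterozygous mice 56 genes were called with age, 27 higher and 29 lower, 19 of them at least 2-fold, and 1236 had an unadjusted p under 0.05; median scaling gave 18 and 37. The count was 18, 1 and 30 without Het_3M 1, 2 and 3, 8, 8 and 37 without Het_12M 1, 2 and 3, and 88 without KO_12M 3. It was 4 with session as a block, 2 with the 3' to 5' ratio as a covariate and 12 without both arrays of disputed age. The actin ratio differed between these groups, at 7.0 against 3.6.

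The age comparison in knockout mice asks what differed between 3 and 12 months where the disease progresses. Oas1e rose by 2.12 ± 0.29, H2-T18 by 2.02 ± 0.42, the lectin Zg16 by 2.00 ± 0.31, Insrr by 1.84 ± 0.30 and the amino acid transporter subunit Slc3a1 by 1.77 ± 0.25. Upp2 fell by 2.88 ± 0.27, Dbp by 2.60 ± 0.55, the clock repressor Per1 by 2.03 ± 0.32, thymidine kinase Tk1 by 1.95 ± 0.25 and the adaptor Ldb1 by 1.77 ± 0.37. With session as a block, which compares KO_12M 3 alone with KO_3M, H2-T18 was 0.45, Insrr 1.25 and Dbp -0.94. Abcb4 had -0.14 ± 0.14 (adjusted p = 0.558). Of the 59 named genes called for age in the knockout, 24 stayed called in every omission of 1 array and 35 lost the call in some.

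Camera called 15 lists lower and none higher with age in the knockout. Complement and coagulation genes had a median of -0.34 (7 of 30 fell; 14 adjusted over the list alone; adjusted p = 4.33e-10), interferon genes -0.71 (6 of 16; 10 adjusted over the list alone; 1.35e-06) and clock genes -0.64 (3 of 12; 7 adjusted over the list alone; 0.00857). C2 fell by 1.02 ± 0.14, Psmb9 by 1.38 ± 0.22 and Psmb8 by 1.36 ± 0.28. Hepatocyte (-0.39), male-biased (-0.30), ribosomal protein (-0.22), MHC class II (-0.21), urea cycle (-0.20), acute phase (-0.16), fatty acid synthesis (-0.15), lipoprotein (-0.15), fatty acid oxidation (-0.15), oxidative phosphorylation (-0.14), cell cycle (-0.12) and immediate early (-0.07) genes were the others. No list passed with an estimated correlation, where the 15 adjusted p ran from 0.371 for complement to 0.565 for acute phase genes. With session as a block the cell cycle median was -0.05, the fatty acid synthesis median -0.10 and Psmb8 -1.35. Median scaling ended the clock (0.0879), cell cycle (0.226), immediate early (0.143), MHC class II (0.0662), acute phase (0.0512) and lipoprotein (0.0505) calls. Quantile normalization ended all calls but complement, interferon, clock and cell cycle, so only complement and interferon genes were called under each of the scalings. The complement median was -0.11 with quantile normalization and -0.67 with median scaling, so its size depends on the scaling, and the interferon median was -0.82 and -1.02. Under quantile normalization the medians of acute phase (0.08), lipoprotein (0.04), ribosomal (0.004), fatty acid synthesis (0.08) and oxidative phosphorylation (0.04) genes turned positive. The session-blocked age effect is that within session 3, where 1 knockout mouse, KO_12M 3, was 12 and 3 were 3 months old. There the clock median was 0.08, the complement median -0.45, the interferon median -0.82 and the hepatocyte median -0.71. KO_12M 3 had a 10th percentile of 9.4, above every other array, and the other fluidics script, so these values are no separate check.

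In the knockout 775 genes were called with age, 462 higher and 313 lower, 110 and 46 of them at least 2-fold, with 2349 at an unadjusted p under 0.05. Median scaling gave 173 higher and 1744 lower and moved the median of all genes from 0.09 to -0.22, and quantile normalization gave 158 and 174. The count was 376 without KO_3M 1, 504 without KO_3M 3, 449 without KO_12M 1 and 445 without KO_12M 3. With the 3' to 5' ratio as a covariate it was 71, without both arrays of the other fluidics script 244 and without those of disputed age 328. The session-blocked fit compares KO_12M 3 alone with KO_3M, so a count from it would say little.

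The interaction asks whether the knockout effect differed between the ages. The knockout effect was lower at 12 than at 3 months for Upp2 (-4.19 ± 0.38), the deubiquitinase Usp2 (-3.32 ± 0.60), Per1 (-2.82 ± 0.45), Map2k6 (-2.19 ± 0.40) and Pck1 (-2.15 ± 0.17), whose other probe set read 0.30. It was higher at 12 months by 2.77 ± 0.47 for the tubulin Tubb2a, 2.01 ± 0.44 for Zg16, 2.01 ± 0.41 for Oas1e, 2.00 ± 0.36 for Nr0b2 and 1.99 ± 0.26 for Cherp, whose other probe set read -0.24. For Abcb4 it was 0.07 ± 0.20 (adjusted p = 0.891).

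Camera called 7 lists with a lower knockout effect at 12 months. Clock genes had a median of -1.35 (2 of 12 passed; 8 adjusted over the list alone; adjusted p = 1.91e-05), interferon genes -0.41 (1 of 16; 5 adjusted over the list alone; 6.93e-05) and urea cycle genes -0.34 (6.93e-05), where the 1 of 22 that passed, Gldc, had a higher effect at 12 months (0.73 and not called with session as a block) and 6 passed adjusted over the list alone. Complement genes had -0.28 (1 of 30; 3 adjusted over the list alone; 6.89e-07), male-biased genes -0.39 (0 of 18; 5 adjusted over the list alone; 0.000513), hepatocyte markers -0.35 (0 of 15; 0 adjusted over the list alone; 0.00119) and acute phase genes -0.10 (1 of 19; 1 adjusted over the list alone; 0.0227). With an estimated correlation none passed, with adjusted p = 0.441 for clock and complement and adjusted p = 0.589 for the other 5. Under the session block, which rests on KO_12M 3 against KO_3M and Het_12M against Het_3M 1, the clock median was -0.48. The medians of the other 6 lists kept their sign there. Quantile normalization ended the hepatocyte (-0.01, 0.632) and acute phase (0.01, 0.814) calls, and median scaling that of acute phase genes (-0.37, 0.0607). The medians under quantile normalization and median scaling were -0.14 and -0.55 for complement, -0.18 and -0.62 for urea cycle, -0.55 and -0.68 for interferon and -0.45 and -0.65 for male-biased genes, and -0.62 for hepatocyte genes under the latter. Acute phase genes did not pass with a stricter filter (0.196), array weights (0.0784) or without the arrays of disputed age (0.057). Without the arrays of the other fluidics script acute phase (0.07, 0.892), male-biased (-0.09, 0.407) and hepatocyte genes (-0.04, 0.235) did not pass. Without KO_12M 3 acute phase (0.578), male-biased (0.0758) and hepatocyte genes (0.0993) did not pass; interferon genes did not without KO_3M 2 (0.0887) or KO_3M 3 (0.18), nor acute phase genes without Het_3M 2 (0.0642), KO_3M 2 (0.0648), Het_12M 2 (0.0829) or Het_12M 3 (0.054).

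The genotype by age interaction called 87 genes, 49 with a higher and 38 with a lower effect at 12 months, 41 and 24 of them by at least 2-fold, with 1327 at an unadjusted p under 0.05. Median scaling gave 23 and 182 and moved the median of all genes from 0.06 to -0.19. With session as a block 14 genes passed, 3 of them among the 87, and of the named genes only Upp2 (-3.48) and Pck1 (-2.14) did. Usp2 was -2.43 there, Per1 -2.14, Map2k6 -1.87, Tubb2a 2.17, Zg16 2.07, Oas1e 1.24, Nr0b2 1.72 and Cherp 1.67. The count was 43, 31 and 26 without Het_3M 1, 2 and 3, 41 without KO_3M 2, 36, 18 and 53 without Het_12M 1, 2 and 3, 45 and 49 without KO_12M 1 and 2, and 20 without both arrays with a fluidics error. Usp2 (0.0529) and Map2k6 (0.0608) lost their calls without Het_12M 2. Oas1e lost its call in 5 of the 12 omissions and Zg16 in 8, with highest adjusted p of 0.0898 and 0.102, both without Het_12M 2.

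**Figure D5:**
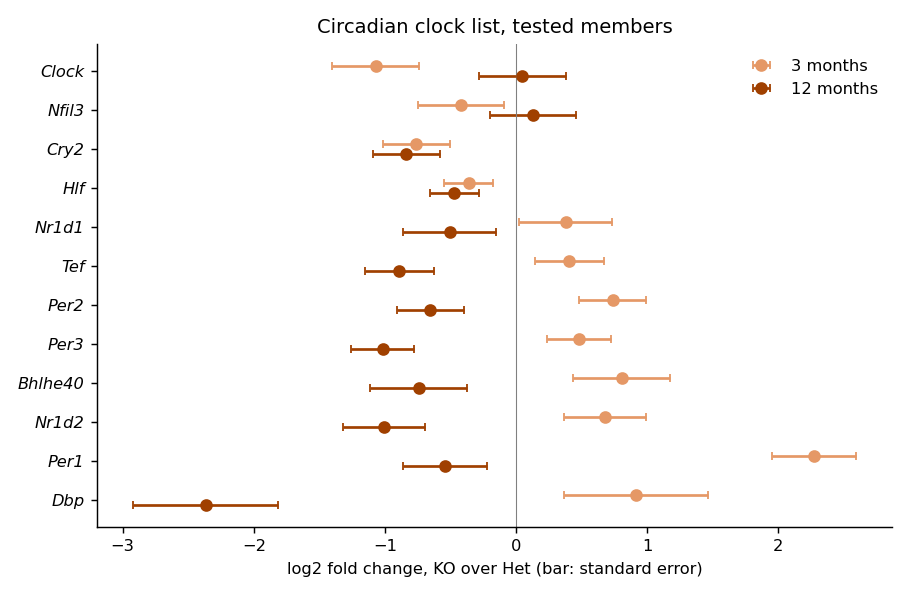
Log2 fold change, knockout over heterozygous, of the 12 tested clock genes at 3 months (light) and 12 months (dark), with limma standard errors (n = 3 mice per group). Per1 (2.28) and Dbp stand highest at 3 months, and Dbp (-2.37) lowest at 12 months.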

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

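The test of hepatocyte share, which first used macrophage markers alone and left 12 months open, its cholangiocyte values and the splits of the arrays were devised after the results they bear on were seen; the fits with the 3' to 5' ratio and the values for probe sets that miss the filter were also added then, and the leading genes, Per1 and Dbp among them, were known when the other predictions were written. The rule for a share kept under a fit first required the share plus its error to stay under 50%. After the clock value was seen it was brought back to the written prediction, a share under 50%, and no other verdict changed.

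A difference between the ages in the knockout effect, tested as an interaction, was found for 87 genes. Higher effects at 12 months were those of Tubb2a (2.769), Zg16 (2.013), Oas1e (2.012), Nr0b2 (1.995), Cherp (1.994), Slc3a1 (1.775), Rbm22 (1.537), Slc5a1 (1.434), Cyp2c38 (1.088) and Gldc (0.918). Lower effects were those of Upp2 (-4.187), Usp2 (-3.32), Per1 (-2.817), Map2k6 (-2.19), Pck1 (-2.15), Thrsp (-1.899), Tk1 (-1.647), Herpud1 (-1.569), Per3 (-1.499), Gys2 (-1.433), Psmb9 (-1.399), Ppara (-1.141), F11 (-0.932) and Serpina3n (-0.793). All 24 kept their sign with session as a block, where only Upp2 and Pck1 were still called. Only 6 of the 24 stayed called in every omission of 1 array, and 18 lost the call in some. In the session-blocked fit Thrsp was -0.583, Per3 -0.595 and Herpud1 -0.846, and other values were Slc3a1 2.26, Rbm22 1.699, Slc5a1 1.711, Cyp2c38 1.417, Gldc 0.727, Tk1 -1.493, Gys2 -1.179, Psmb9 -1.274, Ppara -1.162, F11 -0.96 and Serpina3n -0.867. The lists whose effect differed had medians of -0.098 for acute phase, -0.409 for interferon response, -0.342 for urea cycle and amino acid, -0.279 for complement and coagulation, -0.388 for male-biased, -1.345 for clock and -0.347 for hepatocyte genes. Of 100 splits of the 12 arrays within age, the real one included, 7 called as many genes as the real 87, with 426 the highest, so this count of splits does not exclude chance. The 6 larger splits kept the 3-month genotypes whole and mixed those at 12 months, so their counts carry the knockout effect of 3 months and say little about the interaction. The other splits called at most 41 genes. They mix the genotypes too, which widens the spread, so that count is no chance level either.

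Among 1095 probe sets that name no single gene and were left out of the comparisons, 223 passed the threshold at 3 months (98 higher and 125 lower in the knockout) and 97 at 12 months (59 and 38). They were singled out as signal in values that the comparisons do not use, and no gene is named for them here.

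The first pattern weighed is the difference of the clock genes between the ages. Tissue taken at other times of day in some groups could give it: genes that peak opposite to Dbp moved the other way, by 0.834 ± 0.284 on average over the 2 that passed the filter and by 1.299 ± 0.26 over all 5 on the array, against -1.459 ± 0.322 for the other 10 clock genes. These errors are over genes, not mice. With limma errors the 2 genes were Clock (1.118 ± 0.469) and Nfil3 (0.55 ± 0.463). Neither was called, nor was any of the 5 with no filter. Unequal RNA integrity is argued against, since 101.8 ± 9.1% of the list's median change stayed with the 3' to 5' ratio in the fit. Scan session is not excluded, since only 35.9 ± 18.2% of it stayed with session in the fit. That error leaves out the omissions of Het_3M 1 and KO_12M 3, on which the session-blocked fit rests. Times of day are not given in the sources used here, so a shift of the clock by the knockout itself, collection time and session stay open. Collection time was weighed on the clock list alone. It was not tested for the other genes of the interaction, Upp2, Usp2 and Pck1 among them, and stays open for them too.

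The second pattern is the excess of falls among dim genes at 3 months, 389 against 233 rises among the 2740 dimmest. The authors' scaling, which left the dim end lower on the KO_3M arrays, could account for part of it: 63.8% of these falls stayed called after quantile normalization, but the excess itself was gone (248 falls against 277 rises, median -0.036 against -0.153). Quantile normalization makes the dim ends equal by construction, so neither value decides. With the ratio in the fit 95.4 ± 13.5% of the median fall of these genes stayed, which argues against unequal RNA integrity for the size of their falls. These genes were chosen as called falls, and falls against rises were not counted in that fit. The value therefore does not decide the excess. A biological fall of dim genes, a scaling effect and unequal RNA integrity stay open for it.

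The third pattern is the rise of matrix, macrophage, annexin and cholangiocyte lists. A lower hepatocyte share that raises every other cell type alike was weighed with errors over genes, not mice. The cholangiocyte median exceeded the endothelial one by 1.111 ± 0.404 at 3 and 0.659 ± 0.24 at 12 months. The macrophage median did so by 1.299 ± 0.305 at 3 and by 0.52 ± 0.282 at 12 months, less than 2 errors. The tested markers thus did not rise alike at 3 months, whereas at 12 months only the contrast added later exceeded 2 errors. Markers below the array median on all heterozygous arrays were tested only where knockout arrays reached it, which favours rises. These values therefore do not decide on hepatocyte share. Unequal RNA integrity is argued against, since at least 91.8 ± 14.4% of the pooled effect stayed with the ratio in the fit. With session in the fit at least 108.4 ± 15.4% stayed, but that error rests on 10 omissions. Het_3M 1 and KO_12M 3, which alone link the sessions, could not be left out. A difference between sessions cannot give the medians within session 2 (matrix 0.834, macrophage 1.2, annexin 1.186, cholangiocyte 0.97). Age differed there as well, so a part of session in the knockout effect at either age stays open. More matrix-producing, ductular and macrophage cells in the diseased liver and higher expression per cell stay open, as does an effect of hepatocyte share, since tissue RNA does not separate them.

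For the comparisons of 6 arrays only 10 splits exist, too few for a share under 0.05. The real split was the 1 of 10 with the most calls in each: 1820 against at most 0 at 3 months, 889 against 0 at 12 months, 56 against 2 for age in heterozygous and 775 against 0 for age in knockout mice. Every other split mixes the real groups, so any difference between them, whatever its cause, widens the spread and lowers the calls. The counts of 0 and 2 are therefore no level expected by chance.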

How the results depend on the processing

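The fits with the 3' to 5' ratio as a covariate, without arrays with a fluidics error or another fluidics script, and with session as a random block were chosen after the data were seen. With 3 mice per group and dim signals near background, small changes and dim genes are measured poorly. Where a filter, an omission or a test of fewer groups changes a count, fewer or more genes or arrays were tested; otherwise the cause was not tested. No rescaling changed no named gene and no list.

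For the knockout effect at 3 months (1820 genes) the count was 1070 with a stricter filter, 2749 with every probe set, 1022 without the arrays of disputed age, 291 with session as a block, 559 with the 2-fold filter alone and 679 with the ratio. At 12 months (889) it was 114 with session as a block and 310 with the 2-fold filter.

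For age in heterozygous mice (56) it was 22 with no filter, 93 with a stricter one, 27 with the mean of probe sets, 149 with every probe set, 5 with no intensity trend, 106 with only the groups compared, 191 with array weights, 12 without the arrays of disputed age, 4 with session as a block, 2 with the ratio and 3 without the arrays with a fluidics error. In knockout mice (775) it was 332 with quantile normalization, 1917 with median scaling, 471 with a stricter filter, 238 with only the groups compared, 328 without the arrays of disputed age, 187 with the 2-fold filter, 71 with the ratio and 244 without the arrays of the other script.

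The interaction (87) gave 205 with median scaling, 49 with no filter, 51 with no intensity trend, 173 with array weights, 46 without the arrays of disputed age, 14 with session as a block, 295 with the 2-fold filter, 20 without the arrays with a fluidics error and 50 with session as a random block. Genes shared by both ages (472) numbered 63 with session as a block, 174 with the 2-fold filter and 287 with the ratio. The correlation of the effects (0.602) was 0.536 with no filter, 0.657 with a stricter one and 0.548 with session as a block. With an estimated correlation 2 lists were called at 3 months, 7 at 12 months and 0 for the interaction, where no filter and session as a block gave 11 lists each.

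Mouse numbers as a replicate block moved the interaction count to 46. Of 18 same-numbered pairs of arrays 1 correlated over 0.1 (from -0.199 to 0.179; from -0.186 to 0.124 in the other 36 pairs). Shared deviations of same-numbered mice were thus weak, which does not show whether the numbers pair the mice.

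Leaving out each array gave 1244 to 1938 genes at 3 months, 622 to 910 at 12 months, 1 to 88 and 376 to 723 for age in heterozygous and knockout mice, 18 to 108 for the interaction, 368 to 450 shared genes and a correlation of 0.57 to 0.61. It gave 15 to 19 lists at 3 months, 21 to 23 at 12 months and 4 to 10 for the interaction.

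Some values changed sign. The Abcb4 interaction, 0.07 and not called, was -0.187 with median scaling, -0.01 without KO_3M 1, -0.025 without KO_12M 3 (up to 0.208 without KO_3M 3), -0.016 without the arrays of disputed age and -0.109 without those of the other script. At 12 months Hnf4a was 0.03 with the mean of probe sets and Cyp7a1 -0.046 without KO_12M 1 (up to 0.554 without KO_12M 2). With session as a block, Clock (0.213), Upp2 (-0.082), Per3 (-0.59) and Dbp (-1.626) turned at 3 months, Hspa5 (0.074) at 12 months and Abcb4 (0.062) with age in the knockout. So did the medians of male-biased genes at 3 months (0.148) and of endoplasmic reticulum stress (0.136) and ribosomal protein genes (0.022) at 12 months.

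Over all alternatives, named genes kept direction and side of the threshold in 3444 of 3718 cases at 3 months, 3442 of 3672 at 12 months, 266 of 385 and 1311 of 1770 for age in heterozygous and knockout mice and 558 of 825 for the interaction. Lists did in 463 of 509, 634 of 689 and 184 of 210 for the knockout effects and the interaction. With session as a block 53 of 123 named called genes at 3 months, 40 of 120 at 12 months, 2 of 12 and 28 of 59 for age in heterozygous and knockout mice and 2 of 24 for the interaction were still called, and 121, 119, 12, 59 and 24 kept their sign. With the ratio 89, 107, 1, 12 and 18 were still called and all kept their sign.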

Other observations

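The prediction for the genes beside Abcb4 was written before its test, though Cd36 was known by then as a leading gene, and the counts without Cd36 and with session as a block were added after the result was seen. DNA of the strain the stem cells came from, carried beside the targeted gene, could make neighbours of Abcb4 differ between the genotypes. Of 33 tested genes among the 25 sought on each side, 6 (18.2%) were called the same way at both ages, against 465 of 8184 others (5.7%; one-sided Fisher's exact test, p = 0.0101). They were Cd36 (2.69 at 3 and 2.55 at 12 months), Steap4 (1.57 and 1.20), Sri (1.15 and 0.85), Abcb1a (1.04 and 1.12), Tmem243 (-0.72 and -0.77) and Psmc2 (-0.40 and -0.43). Without Cd36 it was 5 of 32 (15.6%, one-sided Fisher's exact test, p = 0.0336). Only Cd36 was still called at both ages with session as a block, 1 of 33 against 62 of 8184 others (one-sided Fisher's exact test, p = 0.225). All 6 kept their sign in that fit, with Cd36 at 2.21 and 2.35, Steap4 at 2.29 and 1.53, Sri at 1.03 and 0.86, Abcb1a at 0.78 and 1.09, Tmem243 at -0.97 and -0.84 and Psmc2 at -0.46 and -0.47. The call of Abcb1a at 12 months was also lost in 2 omissions of 1 array, and Psmc2 lost calls in 4 omissions at 3 and 5 at 12 months. The excess is in line with carried DNA, but only 8 of the 33 genes lie on 1 of the sides, neighbours can share regulation, and the strain background is not given in the sources used here, so an effect of the knockout on these genes stays open.

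The fluidics log showed an error on Het_12M 1 and Het_3M 2, and another script was used for KO_12M 3 and KO_3M 1. The highest signal on KO_12M 3 was 6328.3.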
